A study of Mus musculus with 24 samples.

How the data were processed

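The 24 libraries were bulk RNA sequencing of primary cells from the hindlimb muscle of newborn mice, per the labels' protocols. Cells came from C57 mice (C57BL/10) and from mdx mice of the same background, which carry a mutation of the dystrophin gene Dmd. Myotubes, the multinucleate cells formed when muscle precursors fuse, were kept in medium with charcoal-stripped horse serum and received 1 µM aldosterone or 0.001% DMSO for 48 h. They were then given fresh medium, which was collected as conditioned medium over 15 h before the myotubes were lysed. No measurement of hormone left in that medium is given, so a change in fibroblasts can stem from the myotubes or from aldosterone carried over. Fibroblasts received the conditioned medium of treated myotubes of their own genotype for 24 h, so the genotype of the fibroblast and that of its medium cannot be separated. The 8 groups (cell type by genotype by treatment) held 3 libraries each, numbered as biological replicates 1 to 3.

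The deposited counts are whole numbers of reads per gene, made with featureCounts version 1.5.0-p3 on the mouse build mm39, per the submitters' processing notes. Libraries were made from poly(A) RNA with a non-directional kit, so reads of overlapping or antisense genes cannot be told apart. The aligner and the annotation release are not given in the sources used here. The deposited FPKM values (fragments per kilobase and total) equal the counts divided by gene length and library total, times 1 constant per library, and were not used for tests. The count table holds 56748 genes, with gene symbols, Ensembl identifiers, coordinates and gene types as deposited, and 0 columns without a sample.

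Counts were analysed in R 4.3.3. For each cell type, the 12 libraries were fitted together with edgeR 4.0.16: genes with too few counts were removed by its default filter, libraries were scaled by TMM, and each comparison was tested with edgeR's quasi-likelihood test (robust) with Benjamini-Hochberg adjustment over all genes kept. A gene passed at an adjusted p below 0.05. The filter kept 15763 genes in myotubes, 16671 in fibroblasts and 17864 in the comparison of both cell types. The standard error of a log2 change was taken as its size divided by the square root of the test's F, which is an approximation. Levels are TMM-scaled CPM (counts relative to the scaled library total), as mean ± SD. For each cell type and treatment or genotype the comparisons were aldosterone against vehicle in C57, in mdx and as the mean of both genotypes, the difference of that effect between genotypes, and mdx against C57 under each treatment. Myotubes were also compared with fibroblasts in C57 under vehicle.

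A further 35 gene lists, covering hormone response, muscle, matrix, signalling, stress, metabolism and markers of other cell types, were written before the data were examined, as were the design, the comparisons and most alternative settings. Of these lists, 34 had members among the genes tested. Each was tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. A further planned list test was fry of limma. Counts of called members are given adjusted over all genes and adjusted over the list alone.

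Named genes followed a rule written before the data were examined. In each comparison it takes the 6 largest increases and 6 largest decreases among called protein-coding genes with a mean of at least 5 CPM in 1 group and no overlap between the groups' libraries. It adds up to 4 called members of each list by smallest adjusted p, a fixed set of hormone, dystrophin and fibrosis genes (Dmd, Nr3c2, Nr3c1, Hsd11b1, Fkbp5, Per1, Tsc22d3, Sgk1, Col1a1, Ccn2, Postn and Acta2), and the 5 genes with the smallest p where few or no genes met the other parts. Of genes called in both genotypes it takes the 10 with the largest mean change. Genes named outside the rule, such as single markers of other cell types, were chosen after their values were seen.

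Vehicle and aldosterone cultures share replicate numbers, and whether a number marks a shared preparation is not given in the sources used here. The pairing was therefore checked in the counts, before the calls of the fits were compared, as the correlation of same-numbered libraries' deviations from their group means. In myotubes every pair correlated, from 0.359 to 0.704 in C57 and from 0.482 to 0.673 in mdx, and each library correlated best with its own number in 3 of 3 pairs. For myotubes the aldosterone comparisons are therefore given with the culture as a block, beside the counts without it. C57 cultures 2 and 3 were told apart less clearly. C57 vehicle replicate 2 correlated at 0.350 with aldosterone replicate 3 (0.495 with its own number). Vehicle replicate 3 correlated at 0.256 with aldosterone replicate 2 (0.359 with its own number). For C57 culture 1 the best other value was -0.475, and for mdx culture 2 it was -0.161. In fibroblasts the mdx pairs correlated (0.106 to 0.299) and the C57 pairs did not (-0.0176 to 0.121), so the unpaired fit was kept.

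The procedure was tested on simulated counts with 200 genes changed by known folds in the C57 aldosterone comparison. In myotubes (15590 genes) it recovered 29.9% of genes changed 1.5-fold, 56.7% changed 2-fold and 92.4% changed 4-fold without the culture block, and 70.1%, 86.6% and 100% with it. False calls were 0 of 119 without the block and 11 of 182 with it. The myotube counts were simulated from the fit with the culture block, so they hold culture effects by construction. Their gain with the block does not test whether the real cultures are paired. In fibroblasts (16397 genes) the recovery was 70.1%, 82.1% and 97.0%, with 10 false of 176 calls. Camera called the changed list and 0 of 100 random lists. The simulated genes varied independently, so this does not test the preset correlation for lists whose genes move together.

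The alternative settings chosen then were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no filter on low counts, a fold above 2, the groups of 1 comparison alone, the replicate block, an estimated correlation in the list tests, and leaving out each library in turn. Alternatives chosen after seeing the data left out each paired culture, a pair of fibroblast libraries, the 3 male fibroblast libraries, a pair of myotube cultures, or the genes on X and Y, or took the 3 deepest fibroblast libraries as a block, or took the share of male cells as a covariate (transcripts of Ddx3y, Eif2s3y, Kdm5d and Uty per library total, relative to the mean of the 3 male fibroblast libraries). DESeq2 size factors moved the median of all genes by at most 0.00525 on the log2 scale relative to TMM, and 0 called lists changed the sign of their median. Gene coordinates are those of the deposited table on mm39. FPKM values, splicing, and sequence reads were not analysed here. Results for a few genes are not reported here.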

Results

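Gene expression was measured in cultured mouse muscle cells to follow a hormone signal from muscle fibres to the fibroblasts around them. Myotubes of C57 and of dystrophin-mutant mdx mice received aldosterone, a mineralocorticoid hormone, or vehicle. Fibroblasts received the medium that those myotubes had conditioned. The 24 libraries formed 8 groups of 3. Totals ranged from 14133165 to 31144746 counts per library in myotubes and from 16964960 to 42698139 counts in fibroblasts. Levels below are CPM (counts scaled to library size) as mean ± SD over biological replicates, with n = 3 per group, or n = 6 for means of both genotypes. Gene p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and list p-values are from camera. No camera call held with an estimated correlation, so p-values with that correlation stand beside the main lists. That setting called 0 lists even between myotubes and fibroblasts, so it could call little here.

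Dmd, the gene mutated in mdx, checked the genotype labels in every library. Dmd (ENSMUSG00000045103, mm39 chromosome X, 81992476 to 84249747) encodes dystrophin, which links the cytoskeleton of muscle fibres to the matrix. In C57 myotubes it lay at 415, 331 and 355 CPM with vehicle and at 449, 462 and 401 CPM with aldosterone. In mdx myotubes it lay at 32.6, 38.9 and 51.9 CPM with vehicle and at 39.6, 43.3 and 64.8 CPM with aldosterone. Fibroblasts expressed less, with 24.5, 31.4 and 32.2 CPM in C57 with vehicle medium, 31.7, 39.8 and 39.0 CPM in C57 with aldosterone medium, 13.4, 9.09 and 9.41 CPM in mdx with vehicle medium, and 9.60, 7.67 and 9.68 CPM in mdx with aldosterone medium. Within each cell type every mdx library lay below every C57 library.

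Myotubes and fibroblasts were compared in C57 under vehicle to ask which cell each culture held and which carried the receptors of the hormone. The myotube libraries were rich in contractile and sarcomere transcripts and the fibroblast libraries in collagen, matrix and cell cycle transcripts. Myh7 (ENSMUSG00000053093, chromosome 14, 55208141 to 55232083), a slow myosin heavy chain, lay at 2058 ± 141 CPM in myotubes and 0.364 ± 0.131 CPM in fibroblasts (log2 change 12.40, adjusted p = 1.67e-09). Thbs4 (ENSMUSG00000021702, chromosome 13, 92888098 to 92931326), a matrix protein of connective tissue, lay at 0.0113 CPM in myotubes and 223 ± 69.5 CPM in fibroblasts. Pdgfra, a receptor that marks fibroblasts, lay at 10.5 ± 1.01 and 425.5 ± 25.3 CPM. The mineralocorticoid receptor gene Nr3c2 (ENSMUSG00000031618, chromosome 8, 77626070 to 77971641) was low in both, at 4.99 CPM in myotubes and 2.46 CPM in fibroblasts (log2 change 1.01, SE 0.27, adjusted p = 0.00233). The glucocorticoid receptor gene Nr3c1 (ENSMUSG00000024431, chromosome 18, 39543598 to 39652474) was higher, at 83.7 and 128.5 CPM. Hsd11b1, whose enzyme regenerates active glucocorticoid, was higher in myotubes, at 8.14 ± 1.32 against 0.454 ± 0.163 CPM. Over the lists, 39 of 39 sarcomere genes were higher in myotubes (39 also adjusted over the list alone, camera adjusted p = 6.81e-16, adjusted p = 0.372 with an estimated correlation). All 40 cell cycle genes and 41 of 47 matrix structural genes were higher in fibroblasts. In all, 13337 of 17864 genes passed.

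Aldosterone was compared with vehicle in myotubes to ask what the hormone does in the cells that make the conditioned medium. Treated myotubes held more transcripts of steroid-responsive genes, of immediate early genes and of the amino acid stress response. They held fewer transcripts of fast and embryonic myosin heavy chains and of Spp1, which encodes the secreted protein osteopontin. As the mean of both genotypes, 34 genes passed without pairing (18 higher, 16 lower), and 1412 passed with vehicle and aldosterone cultures of the same number paired (693 higher, 719 lower), including all 34. The called genes named for this mean moved the same way in 6 of 6 paired cultures. For those picked as largest changes without overlap between groups this holds by construction. Without pairing, leaving out C57 vehicle replicate 2 or 3, C57 aldosterone replicate 3 or mdx vehicle replicate 3 gave 17, 19, 14 and 21 genes. With pairing, leaving out C57 culture 3 or mdx culture 2 or 3 gave 912, 836 and 739.

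Several of these 34 are genes that steroid receptors act on. Fkbp5 (ENSMUSG00000024222, chromosome 17, 28618068 to 28736501), a receptor chaperone that steroid hormones induce, rose from 16.8 ± 1.68 to 23.0 ± 1.40 CPM (log2 change 0.46, SE 0.06, adjusted p = 3.33e-05 paired). Per1 (ENSMUSG00000020893, chromosome 11, 68986043 to 69000786), a clock gene with steroid response elements, rose from 24.5 ± 1.79 to 34.5 ± 5.79 CPM (log2 change 0.47, adjusted p = 6.2e-06). Gpx3 (ENSMUSG00000018339, chromosome 11, 54793279 to 54801203), a secreted peroxidase, rose from 338 ± 46.2 to 572 ± 73.0 CPM (log2 change 0.76, SE 0.04, adjusted p = 2.49e-11). The clock repressor Nr1d1 rose from 33.3 to 58.0 CPM. Lcn2 (ENSMUSG00000026822, chromosome 2, 32274645 to 32278264), a secreted iron-scavenging protein studied as an aldosterone target in heart and vessel, was counted 0 times in the C57 vehicle libraries and lay at 1.25 ± 0.985 CPM with aldosterone. In mdx myotubes Lcn2 lay at 0.0105 CPM with vehicle and 0.537 ± 0.252 CPM with aldosterone. Hsd11b1 (ENSMUSG00000016194, chromosome 1, 192903942 to 192946383) passed with pairing only and rose from 7.18 ± 1.35 to 14.3 ± 5.86 CPM (log2 change 0.91, adjusted p = 1.8e-05). Nr3c2 itself was lower, at 3.09 ± 0.550 against 4.36 ± 0.930 CPM (log2 change -0.48, adjusted p = 0.0189 paired), while Nr3c1 did not pass (log2 change 0.04, adjusted p = 0.728). Sgk1, the kinase that carries aldosterone's effect on sodium channels in the kidney, did not pass (log2 change 0.17, adjusted p = 0.462). The sodium pump subunit gene Atp1b1 rose by a log2 change of 0.24 (adjusted p = 0.000432), and of 16 sodium and potassium transport genes 2 rose and 2 fell (3 and 2 adjusted over the list alone). Of 31 corticosteroid target genes 9 rose and 3 fell, or 14 and 4 adjusted over the list alone (camera adjusted p = 0.0311; adjusted p = 0.521 with an estimated correlation).

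**Figure D1:**
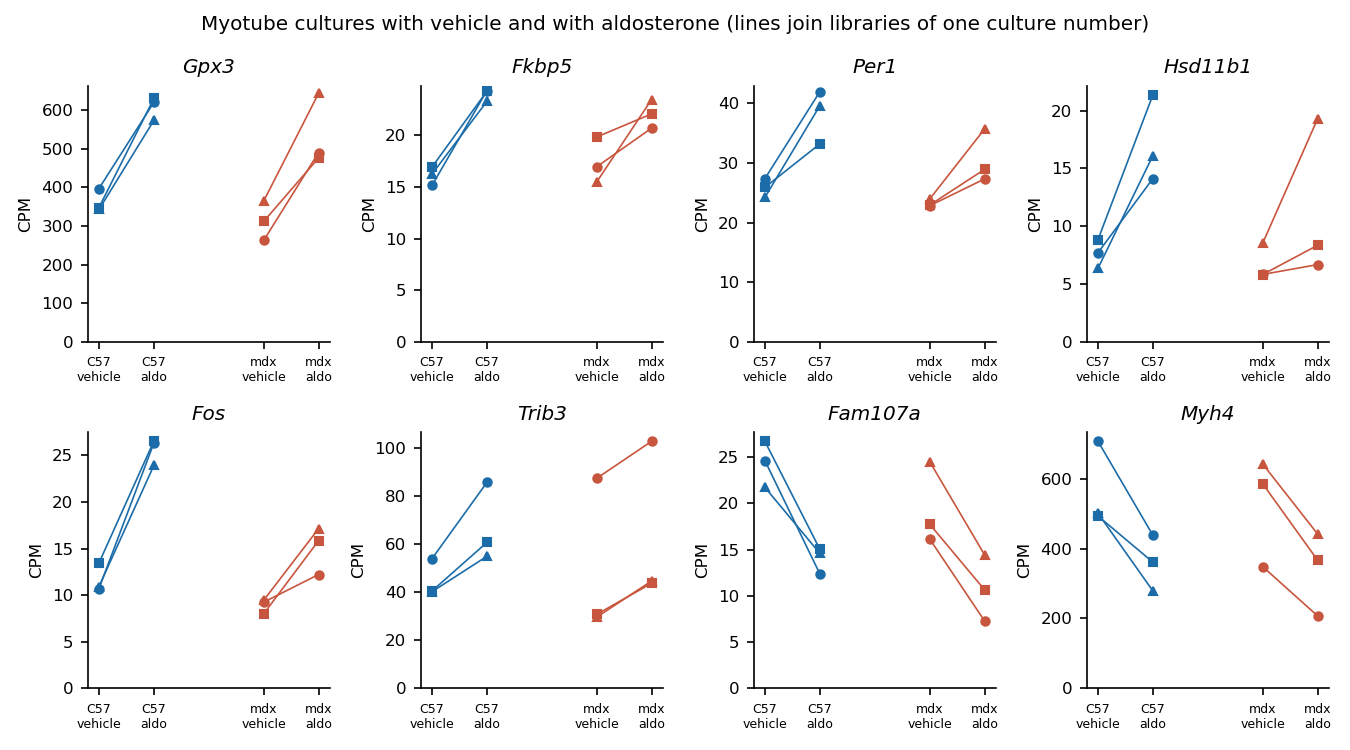
CPM of single genes in each myotube culture with vehicle and with aldosterone, for C57 and mdx, with lines joining cultures of the same replicate number. The 8 genes are Gpx3, Fkbp5, Per1, Hsd11b1, Fos and Trib3, for which all 6 lines rise, and Fam107a and Myh4, for which all 6 fall.

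Immediate early genes and the stress response to amino acid shortage moved together in the treated myotubes. Fos (ENSMUSG00000021250, chromosome 12, 85520664 to 85524047), a transcription factor gene switched on within minutes of stimulation, was measured here after 48 h of hormone and medium collection. It rose from 10.3 ± 1.88 to 20.3 ± 6.06 CPM (log2 change 0.93, SE 0.08, adjusted p = 1.75e-08 paired), and was 1 of 2 genes called in C57 myotubes without pairing, where 0 passed with any 1 of these 6 libraries left out. Egr1 rose from 181 ± 9.84 to 269 ± 43.7 CPM, Ier2 from 33.3 to 55.2 CPM and Junb from 114 to 155 CPM. Of 21 immediate early genes, 12 rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 3.89e-11; adjusted p = 0.521 with an estimated correlation). Trib3 (ENSMUSG00000032715, chromosome 2, 152179342 to 152185952), a pseudokinase induced by the transcription factor ATF4, rose from 47.1 ± 21.6 to 65.5 ± 23.9 CPM (log2 change 0.50, adjusted p = 4.32e-07). Chac1, Phgdh and Atf4 rose by log2 changes of 0.48, 0.30 and 0.28. Of 25 integrated stress response genes 15 rose and 0 fell (20 and 0 adjusted over the list alone; camera adjusted p = 3.05e-13; adjusted p = 0.521 with an estimated correlation). Of 25 heat shock and unfolded protein genes 8 rose, and 13 adjusted over the list alone (camera adjusted p = 2.95e-06; adjusted p = 0.521 with an estimated correlation); Hspb1 rose by a log2 change of 0.37.

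**Figure D2:**
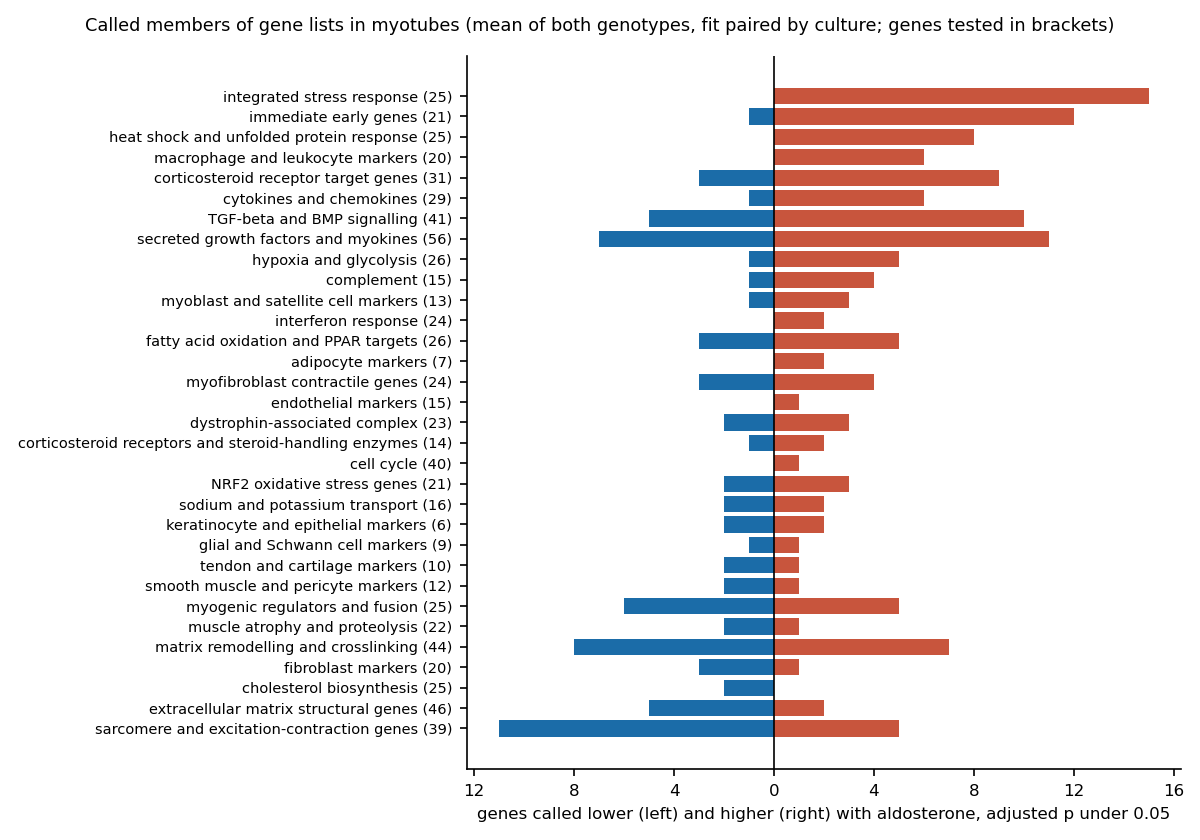
Numbers of list members called higher (right bars) and lower (left bars) with aldosterone in myotubes, as the mean of both genotypes with cultures paired, with the genes tested per list in brackets. The integrated stress response has 15 higher and 0 lower, and sarcomere genes have 5 higher and 11 lower.

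Contractile genes split. Myh4 (ENSMUSG00000057003, chromosome 11, 67128855 to 67151272), the fastest myosin heavy chain, fell from 546 ± 127 to 349 ± 91.7 CPM (log2 change -0.66, SE 0.05, adjusted p = 3.52e-09 paired). Myh3, the embryonic chain, fell from 4625 to 3363 CPM. The calcium pump gene Atp2a1 rose from 812 ± 264 to 1264 ± 404 CPM (log2 change 0.64, adjusted p = 5.74e-09), and Mybpc1 rose from 2010 to 2875 CPM. Of 39 sarcomere genes 5 rose and 11 fell (5 and 12 adjusted over the list alone; camera adjusted p = 0.0222, lower; adjusted p = 0.845 with an estimated correlation). The imprinted transcripts H19 and Meg3 rose by log2 changes of 0.48 and 0.53. Dmd also rose (log2 change 0.25, adjusted p = 0.00111). Among the largest decreases, Entpd3 (ENSMUSG00000041608, chromosome 9, 120368884 to 120397393), which hydrolyses extracellular nucleotides, fell from 5.93 ± 1.69 to 2.25 ± 0.911 CPM (log2 change -1.45, adjusted p = 6.9e-08), Pacsin1 from 23.9 to 13.1 CPM and Fam107a from 21.9 to 12.4 CPM. Among the increases, Col19a1 (ENSMUSG00000026141, chromosome 1, 24300971 to 24626553) rose from 25.7 ± 5.23 to 52.0 ± 16.3 CPM and Nrk (ENSMUSG00000052854, chromosome X, 137815179 to 137911281) rose from 90.3 ± 10.2 to 156.6 ± 16.5 CPM (log2 change 0.80, adjusted p = 6.26e-12).

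Genes for secreted factors are the ones that conditioned medium can carry, and they changed in both directions. Spp1 (ENSMUSG00000029304, chromosome 5, 104582984 to 104588916), a secreted matrix protein and cytokine tied to muscle fibrosis, fell from 1989 ± 607 to 1352 ± 311 CPM (log2 change -0.53, SE 0.04, adjusted p = 1.25e-08 paired). Tgfb3 fell from 244 to 194 CPM, Igfbp5 from 1332 to 928 CPM and Gdf11 from 33.8 to 24.98 CPM. Ccn2, a matricellular protein of fibrosis, rose from 372 ± 105 to 460 ± 116 CPM (log2 change 0.33, adjusted p = 0.0148), and Csf1 from 293 to 362 CPM. Smad7, an inhibitor of TGF-beta signalling, and Ccn1 rose by log2 changes of 0.34 and 0.36. Of 56 secreted growth factor genes 11 rose and 7 fell (15 and 10 adjusted over the list alone), and of 41 TGF-beta and BMP genes 10 rose and 5 fell (13 and 6 adjusted over the list alone; camera adjusted p = 0.0565). The collagen gene Col1a1 (log2 change 0.10, adjusted p = 0.821), Postn (0.29, adjusted p = 0.601) and Acta2 (-0.08, adjusted p = 0.267) did not pass.

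C57 and mdx myotubes shared more called genes than independent lists would, and nearly always in the same direction. In C57 myotubes 785 genes passed with pairing (397 higher, 388 lower) and 2 without, or 0 without pairing when any 1 of the 6 libraries was left out. In mdx myotubes 367 passed with pairing (159 higher, 208 lower) and 0 without (542 at an unadjusted p under 0.05; DESeq2 called 19). Both lists held 104 genes higher and 140 lower, against 4.0 and 5.12 for independent lists of those sizes, and 2 called genes had opposite directions. Leaving out culture 1 or 3 of C57 gave 438 and 401 genes, and leaving out culture 2 or 3 of mdx gave 101 and 149. In C57, in 3 of 3 cultures each, Map2 (ENSMUSG00000015222, chromosome 1, 66214432 to 66481742), a microtubule protein, rose from 3.45 ± 1.01 to 12.7 ± 3.48 CPM (log2 change 1.88, SE 0.13, adjusted p = 2.73e-09). Aldh1a1, which makes retinoic acid, rose from 21.1 ± 5.07 to 57.5 ± 8.30 CPM, and the stretch-responsive Ankrd2 from 4.31 to 13.1 CPM. In mdx, again in 3 of 3 cultures, Clca3a1 (ENSMUSG00000056025, chromosome 3, 144435438 to 144466738), a secreted regulator of chloride channels, rose from 9.43 ± 3.37 to 34.3 ± 7.24 CPM (log2 change 1.84, SE 0.19, adjusted p = 0.00635). Folh1 rose from 12.2 ± 6.52 to 29.6 ± 12.5 CPM (log2 change 1.32, adjusted p = 8.39e-09). Fkbp5 passed in C57 (log2 change 0.57, adjusted p = 0.000243) and not in mdx (0.34, adjusted p = 0.0526), and its difference between genotypes was not called.

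The difference of the aldosterone effect between genotypes asks whether myotubes of the mdx line answer the hormone otherwise. With pairing 7 genes passed (6 with a more positive change in mdx, 1 with a more negative one) and 0 without (152 at an unadjusted p under 0.05). Lpl (ENSMUSG00000015568, chromosome 8, 69333143 to 69360100), the lipase that takes up fat from lipoproteins, fell in C57 from 55.9 ± 22.4 to 38.9 ± 17.2 CPM and rose in mdx from 12.8 ± 8.96 to 18.1 ± 10.2 CPM, in 3 of 3 cultures each (difference 1.10, SE 0.13, adjusted p = 0.000385). Ptgs2 (ENSMUSG00000032487, chromosome 1, 149975782 to 149983978), which makes prostaglandins, rose in C57 from 51.1 to 69.05 CPM and had a log2 change of -0.10 in mdx (difference -0.56, adjusted p = 0.0227). The remaining 5 are leukocyte genes, among them Tyrobp (ENSMUSG00000030579, chromosome 7, 30113185 to 30117010) and C1qc. In mdx, 5 of 20 macrophage markers rose with pairing (12 adjusted over the list alone; camera adjusted p = 5.24e-16; adjusted p = 0.40 with an estimated correlation), but these genes lay at 5.91 CPM for Tyrobp in mdx aldosterone culture 2 alone, against 0.882 CPM in its vehicle partner. Without mdx culture 2, 2 genes passed, Lpl and Aldh1a1; without C57 culture 1, mdx culture 1 or mdx culture 3 the count was 13, 16 and 23.

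**Figure D3:**
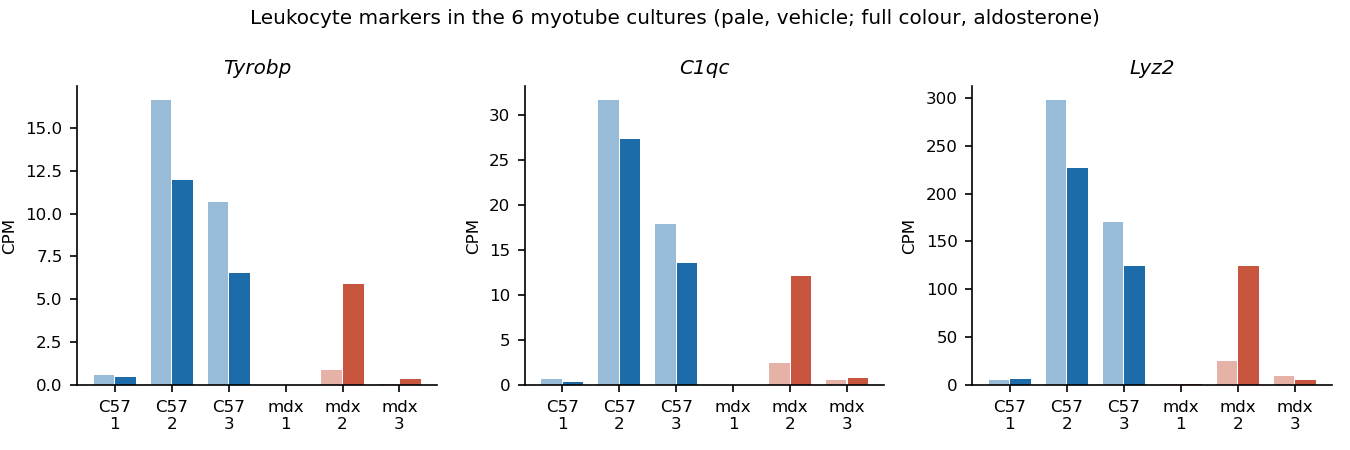
CPM of Tyrobp, C1qc and Lyz2, markers of leukocytes, in each myotube culture, with pale bars for vehicle and full bars for aldosterone. C57 cultures 2 and 3 carry the highest levels, with Tyrobp at 16.6 and 10.7 CPM with vehicle, and in mdx culture 2 it lies at 0.882 CPM with vehicle and 5.91 CPM with aldosterone.

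Myotubes of mdx and C57 mice were compared to ask how the lines differ before and after hormone. Dystrophin deficiency is confounded with other differences between the lines, so its own effect was not tested. The mdx myotubes lacked most Dmd transcript and Esm1, carried Tlr4 transcripts that were not detected in C57, and held more Spp1. As lists, sarcomere and myogenic genes lay lower and matrix and fibroblast genes higher in mdx, with 0 members of these lists called under either treatment and no list called with an estimated correlation. In all, 57 genes passed with vehicle (22 higher in mdx, 35 lower) and 49 with aldosterone (19 higher, 30 lower). The libraries of the genotypes did not overlap for any called gene named for these comparisons, though the naming rule asked for this of the largest changes. Dmd was lower in mdx by a log2 change of -3.16 with vehicle (41.2 ± 9.84 against 367 ± 43.4 CPM, SE 0.21, adjusted p = 5.8e-05) and -3.15 with aldosterone (adjusted p = 5.86e-05). Tlr4 (ENSMUSG00000039005, chromosome 4, 66745821 to 66848521), the receptor of bacterial lipopolysaccharide, was counted 0 times in all C57 libraries and lay at 21.6 ± 1.25 CPM in mdx with vehicle, at least 111-fold higher over both treatments against a floor of 3 counts per library. Esm1 (ENSMUSG00000042379, chromosome 13, 113346193 to 113354632), a secreted proteoglycan of vessel walls, lay at 0.586 ± 0.255 CPM in mdx and 18.6 ± 9.49 CPM in C57 (log2 change -5.09, SE 0.56, adjusted p = 0.00364). Glipr2 lay at 29.1 ± 8.30 against 6.61 ± 1.68 CPM (log2 change 2.14, adjusted p = 0.00558), and Cd59a, which blocks complement on cell membranes, at 19.5 against 6.80 CPM. Fgf6, a growth factor of muscle repair, lay at 2.33 against 10.0 CPM (log2 change -2.04, adjusted p = 0.026). Spp1 lay at 2534 against 1445 CPM (log2 change 0.81, adjusted p = 0.00546).

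With vehicle, the sarcomere list had a median log2 change of -0.31 in mdx (0 of 39 called, 0 higher and 3 lower adjusted over the list alone; camera adjusted p = 9.46e-08; adjusted p = 0.637 with an estimated correlation). The matrix structural list had a median of 0.80 (0 of 46 called; camera adjusted p = 5.15e-08; adjusted p = 0.637 with an estimated correlation) and the fibroblast marker list 1.20 (0 of 20 called, also adjusted over the list alone; camera adjusted p = 1.85e-06; adjusted p = 0.637 with an estimated correlation). The list of myogenic regulators and fusion genes had a median of -0.24 (0 of 25 called, also adjusted over the list alone; camera adjusted p = 6.18e-05; adjusted p = 0.637 with an estimated correlation). Col1a1 lay at 1143 ± 707 CPM in mdx and 360 ± 181 CPM in C57 and did not pass (log2 change 1.66, adjusted p = 0.271). Endothelial markers had a median of -1.16, with 0 called of 15 and 6 lower adjusted over the list alone. The leukocyte marker Tyrobp lay at 0.598, 16.6 and 10.7 CPM in C57 vehicle cultures 1 to 3 and at 0, 0.882 and 0.0750 CPM in the mdx ones. Fos, measured with aldosterone, was lower in mdx (15.1 ± 2.55 against 25.6 ± 1.45 CPM, log2 change -0.76, adjusted p = 0.0402). The counts changed when single libraries were left out, where fewer libraries also lower the power. With vehicle they were 35, 21 and 21 without C57 replicate 1, 2 or 3 and 24, 20 and 104 without mdx replicate 1, 2 or 3. With aldosterone they were 15, 23 and 12 without C57 replicate 1, 2 or 3 and 22 and 25 without mdx replicate 2 or 3. Without the male myotube cultures, C57 culture 1 and mdx culture 2, the counts under both treatments rose, as given in the part on processing.

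**Figure D4:**
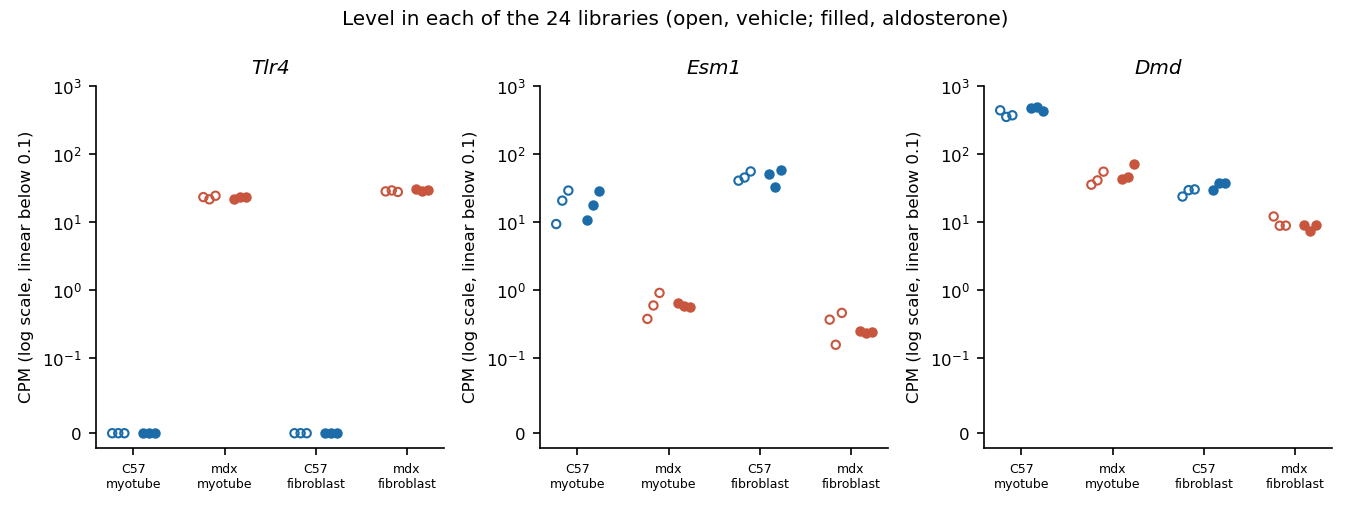
CPM of Tlr4, Esm1 and Dmd in each of the 24 libraries scaled together, on a log axis that is linear near 0, by cell type and genotype (open points, vehicle; filled points, aldosterone). Tlr4 is at 0 in all 12 C57 libraries, and Dmd lies at 351 CPM or more in every C57 myotube library and at 70.1 CPM or less in every mdx myotube library.

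Fibroblasts given medium of aldosterone-treated myotubes were compared with fibroblasts given medium of vehicle-treated myotubes to ask whether the hormone changes what muscle cells signal. As a mean of both genotypes, Ccn3 rose and Zfp469 fell, and cell cycle, amino acid stress and matrix lists moved upward in small steps. Ccn3 (ENSMUSG00000037362, chromosome 15, 54609098 to 54617435), a secreted matricellular protein that opposes Ccn2, rose from 205 ± 25.4 to 279 ± 25.6 CPM (log2 change 0.45, SE 0.05, adjusted p = 0.00591), with every aldosterone library above every vehicle library. Zfp469 (ENSMUSG00000043903, chromosome 8, 122985359 to 122999389), a regulator of collagen genes, fell from 143 ± 21.4 to 106 ± 14.4 CPM (log2 change -0.44, adjusted p = 0.039). These 2 were all that edgeR called of the mean (2540 genes at an unadjusted p under 0.05; DESeq2 called 290). In C57 and in mdx fibroblasts edgeR called 0 genes (1996 and 818 at an unadjusted p under 0.05; DESeq2 called 71 and 0), and the difference between genotypes held 0 (391; DESeq2 called 0).

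The list tests of the mean moved together despite the few single genes. Cell cycle genes had a median log2 change of 0.22 (0 of 40 called, 27 higher adjusted over the list alone; camera adjusted p = 2.63e-16; adjusted p = 0.642 with an estimated correlation). Integrated stress response genes had a median of 0.17 (4 of 25 higher adjusted over the list alone; camera adjusted p = 3.83e-06; adjusted p = 0.642 with an estimated correlation). Matrix structural genes had a median of 0.19, with 3 of 47 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.000129; adjusted p = 0.810 with an estimated correlation). TGF-beta and BMP genes did not move as a list (camera adjusted p = 0.973), though 1 was higher and 6 lower adjusted over the list alone. Col1a1 (log2 change 0.25, adjusted p = 0.476), Acta2 (0.21, adjusted p = 0.537), Postn (0.19, adjusted p = 0.734) and Ccn2 (0.04, adjusted p = 0.921) did not pass. Fkbp5, higher in the hormone-treated myotubes, did not pass in fibroblasts (-0.17, adjusted p = 0.247).

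The fibroblast counts rested on single libraries, most of all on mdx aldosterone replicate 2. Without mdx aldosterone replicate 2, 44 genes passed in C57, 24 in mdx and 950 as the mean of both genotypes (475 higher, 475 lower); without mdx vehicle replicate 2 the mean gave 21, and without both mdx aldosterone replicate 2 and C57 vehicle replicate 1 the counts were 50, 303 and 774. Sex is not balanced in the fit without mdx aldosterone replicate 2: by Y-linked transcripts C57 vehicle replicate 1 and mdx vehicle replicate 2 are male, as is the library left out, and C57 vehicle replicate 3 and aldosterone replicate 1 hold a share of male cells (0.346 and 0.148). With that share as a covariate 259 genes passed for the mean, of which 234 were among the 950 in the same direction. All 950 kept their direction with the covariate, with a median ratio of log2 changes of 0.898. These genes were picked in the same libraries, so kept directions were likely and do not weigh against sex. The covariate also lowers power where sex is not balanced, so the lost calls do not decide whether sex carried the changes. Without the 3 male libraries 774 passed, of which 585 were among the 950. All 948 of the 950 that were tested there kept their direction, with a median ratio of log2 changes of 0.906, again in libraries used to pick them. Both of these fits also leave out mdx aldosterone replicate 2. With that library kept and the share of male cells as a covariate 2 genes passed, so the 950 rest on leaving it out. In the fit without mdx aldosterone replicate 2 alone (5 aldosterone and 6 vehicle libraries), called cell cycle and amino acid stress genes rose, and growth factor, TGF-beta and matrix remodelling genes went both ways. Of 58 secreted growth factor genes 7 rose and 6 fell (11 and 9 adjusted over the list alone), of 41 TGF-beta and BMP genes 8 and 7 (10 and 11 adjusted over the list alone), and of 44 matrix remodelling genes 5 and 5 (11 and 9 adjusted over the list alone). Kcnh2 fell from 15.0 ± 1.00 to 7.79 ± 1.39 CPM (log2 change -0.99, SE 0.10, adjusted p = 0.000297), and Bmp2 from 17.7 to 10.2 CPM, with no overlap between libraries. Vegfa fell from 242 ± 22.0 to 180.0 ± 12.8 CPM (log2 change -0.44, adjusted p = 0.000955), Tgfb1 from 104 ± 16.5 to 77.8 ± 5.80 CPM (log2 change -0.42, adjusted p = 0.01), and Spp1 from 7245 ± 1408 to 4528 ± 474 CPM (log2 change -0.67, adjusted p = 0.0256). Igfbp2 rose from 389 ± 115 to 899 ± 191 CPM (log2 change 1.19, adjusted p = 0.0411), Omd, a small matrix proteoglycan, from 8.45 to 18.2 CPM, and the matrix genes Sparc and Ogn from 3462 to 4572 and from 630.3 to 1016 CPM. The receptor gene Tgfbr2 rose from 313 to 399.9 CPM. Of 47 matrix structural genes 8 rose and 2 fell (21 and 3 adjusted over the list alone). Cell cycle genes included Top2a, Aurkb and Mcm5 among 11 of 40 higher and 0 lower (33 and 0 adjusted over the list alone; camera adjusted p = 2.87e-15; adjusted p = 0.503 with an estimated correlation). Asns and Psat1, which make amino acids, rose by log2 changes of 0.38 and 0.43, among 7 of 25 integrated stress response genes higher and 0 lower (9 and 0 adjusted over the list alone). Of these genes Igfbp2, Bmp2, Tgfb1 and Spp1 did not pass with the share of male cells as a covariate (adjusted p = 0.135, 0.0548, 0.0506 and 0.103), and Igfbp2 did not pass without the male libraries (adjusted p = 0.0562). All of them kept their direction with the covariate, where the log2 change of Igfbp2 was 0.98 and that of Bmp2 went from -0.85 to -0.75. Col1a1 did not pass in the fit without mdx aldosterone replicate 2 alone (0.34, adjusted p = 0.196).

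**Figure D5:**
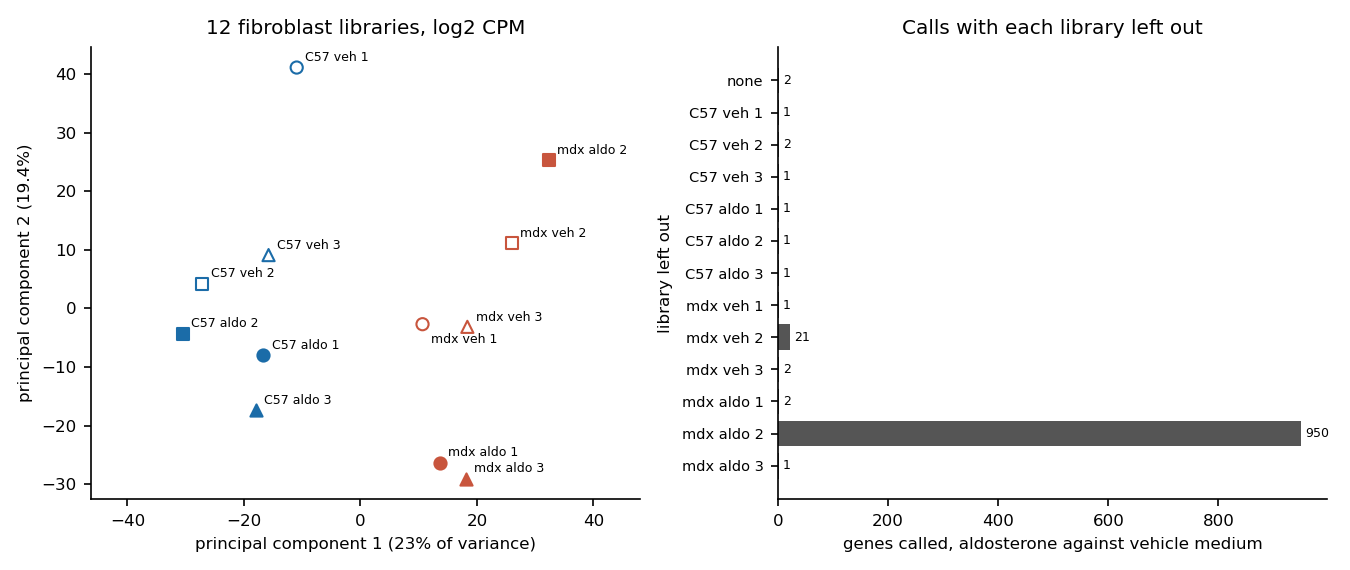
Principal components 1 (23.0% of variance) and 2 (19.4%) of the 12 fibroblast libraries, by genotype and treatment, and genes called for the mean effect of aldosterone medium with each library left out. The libraries mdx aldosterone replicate 2 and C57 vehicle replicate 1 lie highest on component 2, and leaving out the former gives 950 genes.

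Fibroblasts of mdx and C57 mice were compared, each in the medium of its own genotype's myotubes, to ask what sets mdx fibroblasts apart. The mdx fibroblasts held more mitotic transcripts and the homeobox genes Irx3 and Irx5, and less of the follistatin transcript Fst. With vehicle medium 184 genes passed (86 higher in mdx, 98 lower) and with aldosterone medium 205 (99 higher, 106 lower). For the called genes named here the libraries of the genotypes did not overlap, though the naming rule asked for this of the largest changes. Tlr4 lay at 30.3 ± 0.919 CPM in mdx and was counted 0 times in C57, at least 186-fold higher over both media against a floor of 3 counts per library. Esm1 lay at 0.352 ± 0.171 against 49.8 ± 8.65 CPM (log2 change -7.31, SE 0.34, adjusted p = 2.05e-06), and Dmd at 10.6 ± 2.39 against 29.4 ± 4.23 CPM (log2 change -1.48, adjusted p = 0.000342). Irx5 (ENSMUSG00000031737, chromosome 8, 93084253 to 93102914) lay at 18.5 ± 1.91 against 4.10 ± 0.0905 CPM (log2 change 2.17, adjusted p = 3.34e-08) and Irx3 at 108 ± 23.9 against 28.9 ± 2.86 CPM. Cdk1 (ENSMUSG00000019942, chromosome 10, 69170976 to 69188768), the kinase that drives mitosis, lay at 64.9 ± 8.38 against 29.1 ± 2.24 CPM (log2 change 1.17, adjusted p = 8.19e-06), and 5 of 40 cell cycle genes were called higher (27 adjusted over the list alone; camera adjusted p = 3.05e-22; adjusted p = 0.382 with an estimated correlation). Fst (ENSMUSG00000021765, chromosome 13, 114588826 to 114595487), the secreted inhibitor of activins and myostatin, lay at 20.5 ± 1.22 against 54.5 ± 8.12 CPM (log2 change -1.41, adjusted p = 0.0174), and the crosslinking enzyme gene Loxl3 at 331 against 547 CPM. Loxl3 was the only one called of 44 matrix remodelling and crosslinking genes with vehicle medium (2 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.0437, lower; adjusted p = 0.601 with an estimated correlation). In aldosterone medium 2 of 24 myofibroblast genes were called lower, Synpo2 and Cdh2 (14 adjusted over the list alone; camera adjusted p = 1.14e-14; adjusted p = 0.315 with an estimated correlation), and Acta2 did not pass (970 against 1774 CPM, log2 change -0.87, adjusted p = 0.0934). The counts fell to 107, 93 and 117 with vehicle medium without C57 replicate 2, mdx replicate 2 or mdx replicate 3, and to 98, 95, 89 and 130 with aldosterone medium without C57 replicate 1, 2 or 3 or mdx replicate 3. They rose in both media with the share of male cells as a covariate or the 3 deepest libraries as a block, as given in the part on processing.

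Across genes of at least 1 CPM, aldosterone's log2 changes in C57 and mdx correlated at 0.320 in myotubes (Spearman 0.369) and at 0.385 in fibroblasts (Spearman 0.462), with genes not being independent replicates. The correlation depended on that limit: over genes of at least 10 CPM it was 0.556 in myotubes and 0.649 in fibroblasts. Between myotubes and fibroblasts of the same genotype the correlation was 0.0956 in C57 and 0.0369 in mdx (0.111 and 0.0569 at 10 CPM), and its sign changed in C57 without, among others, vehicle replicate 1 of the myotubes (-0.125). Of genes that separated the genotypes with vehicle, 9 were higher and 12 lower in mdx in both cell types, against 0.108 and 0.176 for independent lists over 14627 genes. These shared genes included Tlr4, Glipr2, Cd59a and Glrx among those higher, and Dmd, Esm1, Rab6b and Zfp874a among those lower.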

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

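In this part, the tests of marker correlation, of Tlr4 counts, of gene neighbours, of swapped labels, of thinned counts, of the deepest libraries and of male cells were chosen after the result was seen, as were the fit without mdx culture 2 for the difference between genotypes and the fits with the deepest libraries as a block, with the share of male cells and without the male libraries. With vehicle and aldosterone cultures paired, 7 genes drew attention because the test of the difference of the aldosterone effect between genotypes itself passed (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, mdx minus C57 on the log2 scale). The difference was -0.56 for Ptgs2 (SE 0.0961, adjusted p = 0.0227), with changes of 0.47 in C57 and -0.10 in mdx. It was 1.10 for Lpl (SE 0.132, adjusted p = 0.000385), with changes of -0.54 and 0.56 in 3 of 3 cultures each. For the leukocyte genes it was 3.24 for Tyrobp (SE 0.402, adjusted p = 0.000385), 2.29 for C1qc (SE 0.332, adjusted p = 0.00685), 1.98 for Hcls1 (SE 0.359, adjusted p = 0.0416), 1.86 for Csf1r (SE 0.338, adjusted p = 0.0449) and 4.12 for Vav1 (SE 0.772, adjusted p = 0.0499). In that order their changes were -0.57, -0.33, -0.42, -0.35 and -0.25 in C57, where only Tyrobp was called (adjusted p = 0.0378). In mdx they were 2.67, 1.96, 1.56, 1.51 and 3.88. The difference thus also draws on lower values with aldosterone in C57.

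Leukocyte transcripts differed between single myotube cultures. Tyrobp lay at 16.6 and 11.99 CPM in C57 culture 2 with vehicle and aldosterone, at 10.7 and 6.52 CPM in culture 3 and at 0.598 and 0.481 CPM in culture 1, while Lyz2, the most abundant of these markers, lay at 297 and 227 CPM in C57 culture 2. Without mdx culture 2 the markers called higher were 0 of 20 and their median log2 change went from 1.5 to -0.08. This was to count against a rise caused by aldosterone in mdx myotubes, but it shows only that the calls rested on culture 2. The remaining mdx cultures held too few such transcripts to decide. Tyrobp lay at 0 and 0 CPM in culture 1 and at 0.0750 and 0.367 CPM in culture 3, with vehicle and aldosterone. The markers' median pairwise correlation over the 12 myotube libraries was 0.973, which is consistent with leukocytes carried in with single cultures as a candidate explanation. Whether aldosterone acted on such cells within culture 2 stays open, since it is a single pair of libraries.

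The genotypes differed in 21 genes in the same direction in both cell types, among them Dmd. Cells of 1 type carried into the cultures of the other are argued against: the median ratio of the CPM difference, myotubes over fibroblasts, was 1.13, while fibroblast marker genes had a ratio of 0.102. Tlr4 had 0 counts in the 12 C57 libraries together and 292 to 683 counts in mdx myotubes and 540 to 1309 in mdx fibroblasts, consistent with a deletion of Tlr4 in the C57 line as a candidate explanation, since such a deletion is known in a C57BL/10 substrain. Of the 21 genes Dmd was the only one on chromosome X, which argues against variants near the mdx mutation for the others. For variants of the strain elsewhere, 6 of the 21 genes lay within 5 Mb of another of them against a median of 2 in random draws (p = 0.07 by permutation). These 6 lie on chromosomes 4, 13 and 14. They include Tlr4 and ENSMUSG00000121059, which lies within the span of Tlr4, so this pair may be a single locus. Variants of the strain cannot be told apart from an effect of dystrophin loss. An effect of dystrophin deficiency is confounded with the line and was not tested.

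Among the fibroblasts, mdx aldosterone replicate 2 lay apart from the other aldosterone libraries, and the number of genes called for the mean moved most without it: 2 genes passed with every library, 950 without it and 21 without mdx vehicle replicate 2. Swapped labels within mdx culture 2 are argued against, because vehicle replicate 2 scored -0.127 on the scale of the C57 effect, near the other vehicle libraries, whereas aldosterone replicates 1 and 3 had a mean of 0.734 and aldosterone replicate 2 scored -0.326. With C57 vehicle replicate 1 left out of the scale these were 0.0377, 0.874 and -0.188. Other values go with a swap. The correlation of the effect between genotypes was, over 200 splits, highest with the labels of mdx culture 2 exchanged (0.642, and 0.548 with the real labels). An exchange of these labels also gave 141 genes for the mean, where the real labels gave 2. Muscle cells carried into the culture are argued against by sarcomere transcripts at 0.411% of their level in mdx myotubes (0.0308% to 0.339% in the other fibroblast libraries). The number of counts per library is argued against: with every fibroblast library thinned to 16964960 counts, aldosterone replicate 2 scored at most -0.314 in 10 draws, where the mean of replicates 1 and 3 was at least 0.707, and in the draws that were also fitted 889 and 884 genes passed for the mean without it and 2 with it. Its total of 40.8 M counts (40756528) lay within the range of the other fibroblast libraries, which was to count against depth but decides nothing, since C57 vehicle replicate 1 and mdx vehicle replicate 2 (38764711 and 42698139 counts) are about as deep, the other 9 held at most 28391756, and these 3 lay highest on component 2 (41.1 for C57 vehicle replicate 1, 11.1 for mdx vehicle replicate 2 and 25.3). These 3 are also the male fibroblast libraries by Y-linked transcripts, so depth and sex go together. Component 1 over genes at 10 CPM or more and not on X or Y, centred by group, correlated at 0.871 with the share of male cells and at 0.910 with the log2 total. Male cells and a sequencing run or preparation shared by these 3 libraries therefore cannot be told apart as the source of their place; no run is given in the sources used here, and their deviations from the group means correlated at 0.115 to 0.443, while 11 of 51 other pairs between groups reached the lowest of these. A shift common to male cells is argued against for the missing response, because both libraries of mdx culture 2 are male and its change from vehicle to aldosterone along the effect in C57 libraries without Y-linked transcripts was -0.171, against 0.660 and 0.720 in cultures 1 and 3. That C57 effect sets aldosterone replicates 2 and 3 against vehicle replicate 2 alone, so it carries the deviation of a single vehicle library. With the 3 male libraries as a block, or with the share of male cells as a covariate, 2 genes passed for the mean, and without these 3 libraries 774. A culture that did not respond, a response that differs in male cells, or a single wrong label without a partner also stays open, since this is a single pair of libraries.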

How the results depend on the processing

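Alternatives that left out paired cultures, a pair of libraries or cultures, or genes on X and Y, or that took the deepest fibroblast libraries or the share of male cells into the fit, were chosen after the results were seen; the others in this part were planned. Where the text below gives a changed count, the cause was not tested unless stated. Counts are genes passing, in the order C57, mdx, mean of both genotypes, difference between genotypes, then mdx against C57 with vehicle and with aldosterone; the values without any alternative are 2, 0, 34, 0, 57 and 49 in myotubes and 0, 0, 2, 0, 184 and 205 in fibroblasts. Recovery differed between fits with the same groups of 3 libraries. Without pairing, 29.9% of simulated 1.5-fold changes in C57 myotubes were recovered, against 70.1% with pairing and 70.1% in C57 fibroblasts without it. The myotube counts were simulated with culture effects in them, so the gain with pairing was set by construction.

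Pairing by culture (the replicate block) gave 785, 367, 1412 and 7 genes in myotubes, and 433 and 397 for mdx against C57, where same-numbered libraries of the genotypes did not all correlate (-0.0900 to 0.251 with vehicle, -0.164 to 0.331 with aldosterone, each best with its own number in 1 and 2 of 3 pairs). In C57 and mdx fibroblasts the block gave 0 and 0 genes, as without it, and it moved no other count by over 1.5 times. With the block, list tests called 6, 12, 8 and 11 lists for the first 4 myotube comparisons (3, 7, 4 and 4 without) and 11 in C57 fibroblasts (7 without). Genes called in both genotypes in myotubes numbered 244 with the block; called under both treatments for mdx against C57 myotubes, 223; and called in both cell types for mdx against C57 with vehicle, 47. Leaving out C57 culture 1, 2 or 3 from the paired fit gave 438, 857 and 401 genes in C57, 1064, 1713 and 912 as the mean and 13, 7 and 5 for the difference. Leaving out mdx culture 1, 2 or 3 gave 300, 101 and 149 in mdx, 1120, 836 and 739 as the mean and 16, 2 and 23 for the difference; fewer libraries are the construction of these fits.

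Without a filter on low counts the myotube counts were 26, 16 and 84, then 156 and 163 for mdx against C57, and the fibroblast counts were 65, 2 and 215, then 436 and 452. The DESeq2 Wald test gave 59, 19 and 162, then 373 and 487 in myotubes, and 71 and 290 for C57 and the mean, then 457 and 546 in fibroblasts. In simulated C57 fibroblasts that test made 32 false of 211 calls (15.2%). Fitting only the groups compared gave 30 in C57 myotubes, 6 and 23 for mdx against C57 myotubes, and 5 in C57 fibroblasts. Requiring a fold above 2 gave 9 for the myotube mean, 35 and 26 for mdx against C57 myotubes, 0 for the fibroblast mean and 78 and 70 for mdx against C57 fibroblasts, with fewer genes by construction. With an estimated correlation camera called 0 lists in all 13 comparisons, also between the cell types, so that setting could call little here. The planned list test fry called 29 of 34 lists between the cell types. In myotubes it called 6, 1, 6 and 0 lists for aldosterone with the block (0, 0, 1 and 0 without). For mdx against C57 myotubes it called 4 and 3 with the block and 0 without. In fibroblasts it called 0 lists in every comparison, except 1 in C57 with the block.

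Leaving out each library in turn gave 0 in C57 myotubes whichever library was left out, 14 to 47 for the myotube mean, 20 to 104 and 12 to 37 for mdx against C57 myotubes, 0 to 24 in mdx fibroblasts, 1 to 950 for the fibroblast mean, and 93 to 249 and 89 to 170 for mdx against C57 fibroblasts. The libraries that moved a count by over 1.5 times stand beside those counts in the report; further ones are mdx vehicle replicate 3 in mdx fibroblasts (1 gene) and the several fibroblast libraries without which the mean gave 1. The correlation of the aldosterone effect between myotubes and fibroblasts ranged from -0.125 to 0.258 in C57, reversed without myotube C57 vehicle replicate 1 (-0.125) and aldosterone replicate 2 (-0.0119). In mdx it ranged from -0.0308 to 0.0750, reversed without myotube mdx aldosterone replicate 2 (-0.0308) and fibroblast mdx aldosterone replicate 1 (-0.00933); both correlations are near 0.

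Without the pair of fibroblast libraries apart on the principal components (C57 vehicle replicate 1 and mdx aldosterone replicate 2) the fibroblast counts were 50, 303, 774 and 1, and 349 for mdx against C57 with vehicle. With the 3 deepest fibroblast libraries (C57 vehicle replicate 1, mdx vehicle replicate 2 and mdx aldosterone replicate 2) as a block the fibroblast counts were 1, 0, 2, 0, 357 and 274. These are also the male libraries: with the share of male cells as a covariate the counts were 1, 0, 2, 0, 403 and 306, with mdx aldosterone replicate 2 left out as well 7, 18, 259, 0, 505 and 215, and without the 3 male libraries 77, 231, 774, 0, 218 and 356. Without C57 culture 1 and mdx culture 2, the male myotube cultures, mdx against C57 gave 179 and 103. Without genes on X and Y the fibroblast counts were 0, 0, 2, 0, 180 and 194. DESeq2 size factors in place of TMM moved 2 of 673 values of named genes across the threshold. Over the alternatives, named genes kept their direction and side of the threshold in 528 of 644 values with the Wald test, 585 of 649 without a filter, 294 of 673 with the block (372 passed only with it) and 4702 of 5154 with a library left out.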

Other observations

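Of the tests in this part, the splits of the paired cultures for the difference between genotypes, the relabellings that part every mdx pair and the fits that take sex into account were chosen after the result was seen; the fibroblast values without mdx aldosterone replicate 2 come from a planned fit that was looked into after its count was seen. Single genes of sterol synthesis, energy and redox metabolism fell with aldosterone in myotubes, in lists that did not move as a whole (edgeR's quasi-likelihood test, paired, 6 of 6 cultures for each gene). Of 25 cholesterol synthesis genes 0 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.848). Of 26 fatty acid oxidation and PPAR genes 5 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.149), and of 21 NRF2 genes 3 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.322). Dhcr7, the last enzyme of cholesterol synthesis, fell from 75.2 ± 7.68 to 55.8 ± 4.95 CPM (log2 change -0.43, adjusted p = 2.99e-07). The mitochondrial uncoupling genes Ucp2 and Ucp3 fell by log2 changes of -0.51 and -0.43, and Nqo1, a target of the oxidative stress factor NRF2, by -0.47. The fetal acetylcholine receptor subunit Chrng, which marks immature or denervated muscle, fell from 609 ± 70.1 to 489 ± 70.6 CPM (log2 change -0.32, adjusted p = 8.21e-06). The matrix genes Nid2, Tnc and Fbn2 had log2 changes of -0.34, -0.31 and -0.52, while of 46 matrix structural genes 2 rose and 5 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.848).

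In mdx fibroblasts with vehicle medium, single genes of the link between cell and basement membrane and a complement gene differed beyond those of the report, with no overlap between the genotypes' libraries. Lama2, a laminin chain mutated in congenital muscular dystrophy, lay at 24.5 ± 4.44 against 42.1 ± 5.94 CPM (log2 change -0.78, adjusted p = 0.0123), and Cav3 at 3.41 against 1.84 CPM. Of 21 genes of the dystrophin-associated complex 1 was higher and 3 were lower (2 and 3 adjusted over the list alone; camera adjusted p = 0.163). The complement gene C3 was lower by a log2 change of -0.78, and of 14 complement genes 1 was higher and 2 lower (2 and 3 adjusted over the list alone). Without mdx aldosterone replicate 2, aldosterone medium raised the chemokine Cxcl12 from 361 ± 80.7 to 652 ± 94.7 CPM (log2 change 0.85, adjusted p = 0.0459) and the complement inhibitor Serping1 from 4.45 to 10.5 CPM, in 5 aldosterone against 6 vehicle libraries. Sex is not balanced in that fit: with the share of male cells as a covariate Serping1 passed (adjusted p = 0.0356) and Cxcl12 did not (adjusted p = 0.169), and without the 3 male libraries both passed (adjusted p = 0.00304 and 0.0463). With the covariate all 950 genes called in that fit, both of these among them, kept their direction, with a median ratio of log2 changes of 0.898. They were picked in the same libraries, so this was likely and does not weigh against sex.

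X- and Y-linked transcripts showed the sex of the mice. Ddx3y lay at 84.9 and 84.2 CPM in C57 myotube culture 1 with vehicle and aldosterone and at 114 and 131 CPM in mdx culture 2, and below 1 CPM in the other myotube cultures, whose Xist lay from 499.6 to 775 CPM. Among fibroblasts, C57 vehicle replicate 3 and C57 aldosterone replicate 1 held both Xist (871 and 1091 CPM) and Ddx3y (30.9 and 13.3 CPM), while C57 vehicle replicate 1, mdx vehicle replicate 2 and mdx aldosterone replicate 2 held Ddx3y (92.6, 93.4 and 95.3 CPM) with Xist below 1 CPM. Vehicle libraries thus hold more male cells than aldosterone libraries, and more so without mdx aldosterone replicate 2.

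A hypothesis was that aldosterone carried over in the medium acts on the fibroblasts directly. Of the 9 corticosteroid targets called higher in myotubes, 8 had a positive mean change in fibroblasts, which is consistent with aldosterone carried over in the medium, though 0 were called. Without mdx aldosterone replicate 2, 3 of the 9 were called higher (Gpx3 0.68, Serpina3n 0.62 and Tsc22d3 0.30 on the log2 scale), while Fkbp5 had a change of -0.20 (-0.17 with every library). With the share of male cells as a covariate in that fit none of these 3 passed (adjusted p = 0.0614, 0.0516 and 0.157), though their log2 changes were 0.69, 0.55 and 0.25. Without the 3 male libraries Gpx3 and Serpina3n passed and Tsc22d3 did not (adjusted p = 0.0253, 0.0215 and 0.0675). A factor from the myotubes that acts on the same genes may have the same effect and was not tested.

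Other splits of the libraries were counted for each number of genes called. For a single genotype or treatment there are 10 splits of 6 libraries, too few for a share under 0.05. The real count and the highest other were 2 and 0 for aldosterone in C57 myotubes (1 split as large), 0 and 1 in mdx myotubes (10 splits), 57 and 0 for mdx against C57 myotubes with vehicle, 49 and 0 with aldosterone, 0 and 1 for aldosterone medium in C57 fibroblasts, 0 and 14 in mdx fibroblasts, 184 and 0 for mdx against C57 fibroblasts with vehicle medium, 205 and 0 with aldosterone medium, and 13337 and 0 for myotubes against fibroblasts. With pairing, 4 exchanges of labels within cultures are likewise too few, with 785 and 1 in C57 myotubes and 367 and 6 in mdx myotubes.

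For the mean of both genotypes in myotubes, 1 of 100 relabellings, the real one, gave 34 genes or more, and the highest other gave 0. These relabellings ignore the pairing of the cultures, so they do not decide on chance. With pairing, 1 of 32 exchanges, the real one, gave 1412 or more, and the highest other gave 11. This share is under 0.05 and argues against chance, but it is the smallest that 32 exchanges can give. For the fibroblast mean 4 of 100 relabellings gave 2 genes or more, a share under 0.05, but chance is not excluded. The highest other gave 28, several times the real count, and these relabellings ignore the pairing of the mdx libraries. Such a count points to a structure of the samples that was not identified. The 3 male libraries, which are also the deepest, lay on the same side in 18 of the relabellings, of which 14 gave 0 genes, 2 gave 1, and the others 28 and 9. Of the drawn relabellings that did not hold these libraries together, the real one aside, 1 gave 2 genes or more. The highest count, 28, thus came with the male and deepest libraries on the same side. The mdx numbers pair the libraries, and of the 80 relabellings that part every mdx pair 2 gave 2 genes or more; the highest other gave 141, with the labels of mdx culture 2 exchanged. For the difference between genotypes without pairing the real count is 0, so all 100 of 100 relabellings are as large by construction and test nothing; the highest was 1 in myotubes and 141 in fibroblasts, where the relabelling exchanged mdx culture 2. For the 7 genes of that difference with pairing, the 6 myotube cultures were parted 3 against 3; these 10 splits are too few for a share under 0.05, and the highest other gave 2. The correlation of aldosterone's effect between genotypes (log2 of CPM plus 2) was 0.539 in myotubes, as large in 1 of 200 splits (highest other 0.458), and 0.548 in fibroblasts, as large in 4 of 200 (highest other 0.642, with the labels of mdx culture 2 exchanged).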
